A study of Mus with 4 samples.

How the data were processed

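RNA sequencing was carried out on liver sinusoidal endothelial cells (LSECs), the fenestrated cells that line the sinusoids of the liver, from mice treated with carbon tetrachloride (CCl4), a liver toxin. Per the labels, 2 samples came from control mice (CTL) and 2 from Pofut1 knockout mice (P1KO). The gene was deleted in the endothelium. The tissue and cell type labels give liver and LSECs, whereas the extraction protocol in the labels names heart ventricles as the source of the RNA, and this contradiction stays open. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit.

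The authors deposited 1 table of raw counts for the whole series, with whole-number read counts for 54532 Ensembl mouse gene identifiers in 4 columns and no row that names anything other than a gene. Per the submitters' processing notes, the tools included CASAVA, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, and the build was mm10. The annotation release and the strand setting of the counting are not given in the sources used here. How reads of overlapping or near-identical genes were counted is therefore not known, and such reads may be missing or misassigned. All 4 columns were used, and 0 columns were left out. The columns are called CTL1, CTL2, KO1 and KO3, and the libraries carry those names below. CTL1, CTL2 and KO1 match 1 sample title each. The number of KO3 is in no title, since the titles number the knockout samples 1 and 2, so this column was placed in the P1KO group without a sample number. No label says whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

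The deposited table gives identifiers without gene symbols. The gene table used for reference here (assembly GRCm38.p6, 49997 genes) holds symbols but no Ensembl identifiers, and 0 of the 54532 identifiers were matched to a symbol. Pofut1, the fibrinogen chains, the ratio of fibrinogen to hepatocyte transcripts and the 28 gene lists that had been fixed before the data were examined are therefore not analysed here, and the identity of the cells and of the deleted gene was not checked. No coordinates are given, for the same reason.

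Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes with low counts were removed with filterByExpr, which left 15510 genes, libraries were scaled with TMM, and the quasi-likelihood F-test compared P1KO with CTL over all 4 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are P1KO against CTL on the log2 scale, and the standard error of a fold change was computed as its size divided by the square root of F. Levels are CPM scaled with TMM, computed here from the deposited counts. Pairwise differences and correlations between libraries used log2 CPM with a prior count of 2. Genes were split into 7755 less abundant and 7755 more abundant genes at the median abundance over all 4 libraries, 18.9 CPM. The rule for single genes, fixed before the data were examined, took the largest changes in each direction among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM, 12 per direction. Its exclusions by symbol could not be applied, and since no symbols were matched, 2 identifiers per direction are printed and the others are summarised.

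The script was tested on simulated counts for the 15510 tested genes of the P1KO against CTL comparison. They were drawn at the observed means and library sizes, with 1 dispersion trend shared by both groups. The script recovered 26 of 47 genes changed 1.5-fold, 40 of 50 changed 2-fold, 45 of 50 changed 4-fold and 50 of 50 changed 8-fold. Of its 164 calls, 3 were unchanged genes. The real groups differed in spread, with a biological coefficient of variation of 3.23% in CTL and 12.1% in P1KO. The simulation therefore does not show the error rate in these data. The alternatives were DESeq2 size factors, library totals without TMM, DESeq2 1.42.0, limma-voom (limma 3.58.1), 2 other filters on low counts, a minimum change of 1.5-fold, and each library left out in turn. Alternatives chosen after seeing the data were thinning to equal depth, cyclic loess scaling, a separate spread per group and summing the CTL libraries. Cell cycle lists given as Ensembl identifiers by scran 1.30.0 were tested with limma's camera, also after seeing the data.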

Results

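The data comprised RNA-seq read counts of LSECs from CCl4-treated mice. Of the libraries, 2 were from controls (CTL) and 2 from mice with Pofut1 deleted in the endothelium (P1KO). POFUT1 is the enzyme that attaches O-linked fucose to EGF-like repeats, among them those of Notch receptors. The series asks by which genes endothelial POFUT1 acts on the phenotype of LSECs and of hepatic stellate cells, the matrix-producing cells of the injured liver, and its title names fibrinogen synthesis. The comparison that the design implies is P1KO against CTL. The libraries were almost equally deep, with 17464769 counts in CTL1, 17801587 in CTL2, 17918834 in KO1 and 17724765 in KO3. At least 1 read was present for 22089 genes in CTL1, 22100 in CTL2, 21854 in KO1 and 21890 in KO3. The 10 most abundant genes of each library took between 5.56% and 6.23% of its counts. The identifiers were not matched to gene symbols, so Pofut1 and the fibrinogen chains are not analysed here, and genes are described by identifier, level and direction.

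LSECs of the 2 genotypes differed in the level of 3027 of 15510 tested genes, 19.5% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 1501 genes were higher and 1526 lower in P1KO, and 12483 genes did not pass. The rises were mostly small, with a median of 1.32-fold, and the falls were larger, with a median of 1.64-fold. These medians cover called genes only, and a scarce gene needs a larger change to be called. Among the less abundant genes were 639 of the falls and 251 of the rises, so part of the difference in size may stem from this. Among the 622 called genes that changed at least 2-fold, 175 were higher and 447 lower, so that falls made up 71.9% of the large changes. Changes of at least 8-fold were balanced again, with 24 genes higher and 23 lower. For all 3027 called genes both P1KO libraries lay on the same side of both CTL libraries. The same was true of 62.6% of all tested genes. Chance gives 33.3% only if all 4 libraries vary alike and independently. A closer pair raises the chance share, and the CTL libraries were the closer pair, so the 62.6% does not by itself show an effect of genotype.

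In edgeR the number of called genes rested on the closeness of the CTL pair. Without CTL1, 129 genes were called, and without CTL2, 120, since the spread then came from the P1KO pair. Without KO1, 5391 genes were called, and without KO3, 5208, with the spread from the CTL pair alone. With all 4 libraries, limma-voom with a separate spread per group called 2953 genes, 2728 of them among the 3027. That fit still draws on the CTL pair for its spread, so it does not remove this dependence. Without a filter on low counts 1633 genes passed in edgeR. A core of 107 genes was called in the full fit and in each of the 4 fits with a library left out, of which 50 were higher and 57 lower in P1KO. Their changes ranged from 0.77 to 8.04 on the log2 scale in absolute size, with a median of 2.49-fold, and 79 of the 107 changed at least 2-fold. The at least 2-fold calls likewise numbered 38 higher and 52 lower without CTL1, 37 and 51 without CTL2, and 318 and 775 without KO1.

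**Figure D1:**
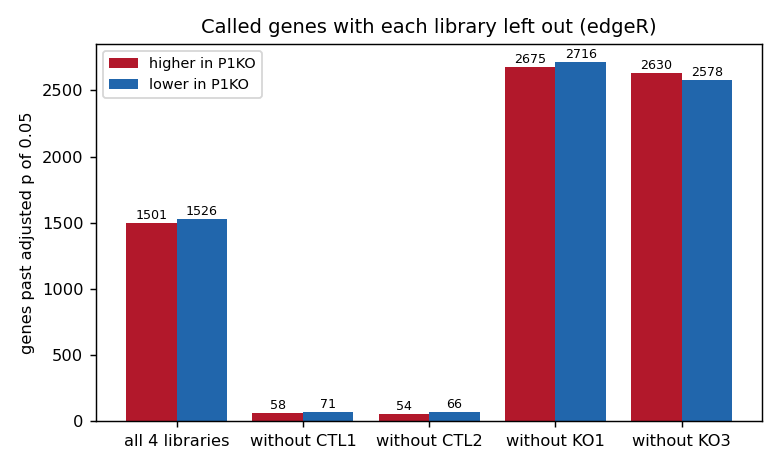
Number of genes past an adjusted p of 0.05 (y axis, edgeR) that were higher or lower in P1KO, with all 4 libraries and with each library left out (x axis). The counts fell to 58 higher and 71 lower genes without CTL1 and rose to 2675 higher and 2716 lower genes without KO1.

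The 12 largest rises lay between 3.20 and 7.42 on the log2 scale and the 12 largest falls between -2.57 and -8.04. In this set, 7 of the 12 rises and 9 of the 12 falls belonged to the core of 107 genes. The largest rise was that of ENSMUSG00000026535, which had 5 reads in each CTL library against 851 in KO1 and 903 in KO3. Its level was 0.282 ± 0.00341 CPM (SD, n = 2) in CTL and 49.5 ± 1.68 CPM (SD, n = 2) in P1KO. The log2 fold change was 7.42, with an adjusted p of 1.76e-06 in edgeR's test. From the summed reads the level was 175-fold higher in P1KO, with a 95% interval of 95.2 to 367 (exact binomial, counting error only). The standard error from F, 0.16, is smaller than this interval implies. The small CTL SD reflects equal counts of 5 reads, so neither value gives the full uncertainty. ENSMUSG00000057465 rose from 2.29 ± 0.467 CPM to 125 ± 67.9 CPM (SD, n = 2 each), a log2 fold change of 5.76 ± 0.47 (SE) with an edgeR adjusted p of 0.000377. The P1KO libraries differed for this gene, at 76.5 CPM in KO1 and 173 CPM in KO3, and its log2 fold change was 5.06 without KO3. Its edgeR adjusted p was 0.0541 without CTL1 and 0.0584 without CTL2.

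The deepest fall was that of ENSMUSG00000037849, which had 167 and 161 reads in the CTL libraries, 1 read in KO1 and 0 in KO3. Its level of 9.26 ± 0.351 CPM (SD, n = 2) in CTL was 328-fold that in P1KO, with a 95% interval of 58.4 to 12987 from the summed reads (exact binomial, edgeR adjusted p of 0.000111). Without KO3 the ratio was 163, with an interval of 29.0 to 6457, and without KO1 it was at least 55-fold higher in CTL, with KO3 taken at 3 counts. ENSMUSG00000073491 had 254 and 328 reads in CTL1 and CTL2, 5 in KO1 and 0 in KO3, which is 116-fold more in CTL with a 95% interval of 49.6 to 360 (exact binomial, edgeR adjusted p of 0.000217). For this gene the ratio was 57.8 without KO3, with an interval of 24.6 to 179, and without KO1 it was at least 97-fold higher in CTL. The intervals cover counting error only. A read count of 0 allows up to 3 counts, 0.169 CPM in KO3, so that a low level of either gene in KO3 was not detectable at this depth. In all, 3 genes had at most 3 reads over both P1KO libraries and a CTL mean of at least 1 CPM, and 5 genes showed the opposite. The labels give neither the strain nor the litter of the mice, so a difference in genetic background between the groups is not excluded for these genes or for the largest rises and falls.

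In the fit to all 4 libraries the direction of the called changes differed with abundance, except for large changes. This split was chosen after the data were seen. Of the 890 called genes among the less abundant genes, those below the median of the tested genes, 639 were lower and 251 higher in P1KO, so that 71.8% were lower. Of the 2137 called genes among the more abundant genes, 887 were lower and 1250 higher, which is 41.5% lower. Among the calls of at least 2-fold, falls were the majority in both, with 322 of 439 (73.3%) of the less and 125 of 183 (68.3%) of the more abundant genes, so the surplus of rises among the more abundant genes came from changes below 2-fold. The median log2 change was -0.10 over all 7755 less abundant genes and 0.04 over all 7755 more abundant genes. Both P1KO libraries showed this. Against the CTL mean, the medians of the less and the more abundant genes were -0.13 and 0.04 for KO1, and -0.07 and 0.03 for KO3. CTL2 against CTL1 gave -0.01 and 0.00, and KO3 against KO1 gave 0.04 and -0.02. Among the more abundant genes the majority turned narrowly to falls in the smaller sets called without CTL1 (53.0% lower) and without CTL2 (54.2% lower). It did so as well with the CTL libraries summed (52.2% lower), against a 1.5-fold minimum change (54.4% lower) and with cyclic loess scaling. Cyclic loess removes trends with abundance by construction, and called 1013 of the more abundant genes lower and 929 higher. Rises remained the majority in the larger sets called without KO1 (43.0% lower) and without KO3 (38.3% lower). Among the less abundant genes falls remained the majority against a 1.5-fold minimum change, with 54 lower and 36 higher (60% lower). Without CTL1 and without CTL2 the shares were 71.4% and 61.5% lower. Too few less abundant genes were called in these 2 sets to show a direction.

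**Figure D2:**
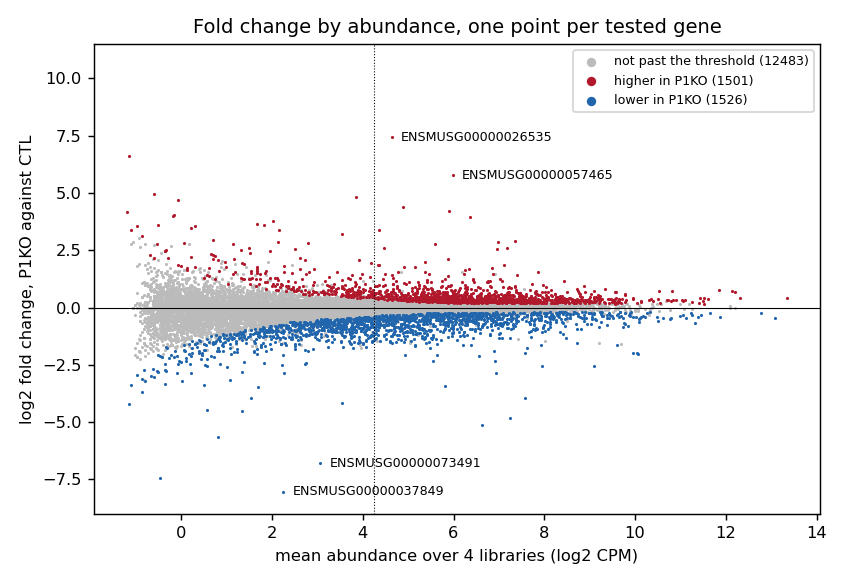
Log2 fold change of P1KO against CTL (y axis) by mean abundance in log2 CPM (x axis), with 1 point per tested gene, coloured by call, and a dotted line at the median abundance. The 4 identifiers named in the text are marked, and called falls outnumber called rises to the left of the line, 639 to 251.

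The contrast was sharpest between genes at 1 to 4 CPM and at 64 to 256 CPM. In the lower class, 164 of 223 called genes were lower in P1KO, and in the higher class 577 of 875 were higher. Called genes were also more frequent among abundant genes, where counting error is smaller. Among the 257 genes above 512 CPM, 159 passed, 87 of them higher and 72 lower, which is 61.9% of that class, against 48 of 1110 genes up to 1 CPM, 4.32%.

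**Figure D3:**
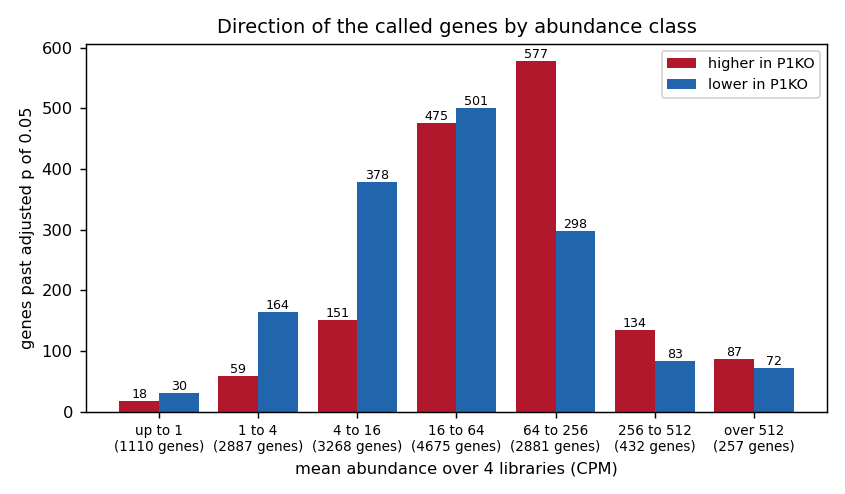
Number of called genes higher or lower in P1KO (y axis, edgeR adjusted p below 0.05) in 7 classes of mean abundance in CPM (x axis), with the number of tested genes under each class. Falls outnumber rises in the 4 classes up to 64 CPM, and rises outnumber falls above 64 CPM.

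The 3027 called genes held 43.7% of all counts in CTL1 and in CTL2, and 43.9% in KO1 and in KO3. The genes called higher took 22.3% and 22.2% of the counts in CTL1 and CTL2, and 28.7% and 29.5% in KO1 and KO3. The genes called lower took 21.4% of the counts in each CTL library, and 15.1% and 14.4% in KO1 and KO3. These shares depended on the called set. The genes called without CTL1 held 2.10% of the counts in CTL1 and 1.47% in KO1, and the core of 107 genes 1.81% and 1.23%. Those called without KO1 held 66.1% in CTL1 and 66.2% in KO1, and those called without KO3 65.3% and 65.9%. The genes were chosen on the same libraries, so the shares describe the size of the shift and are no separate test of it.

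The spread between libraries was unequal between the genotypes. The biological coefficient of variation was 3.23% between the 2 CTL libraries and 12.1% between the 2 P1KO libraries. Both pairs differed by more than the sampling noise of independent reads, which gives a chi-square per gene of 1. The value was 2.08 for CTL and 10.2 for P1KO. The log2 changes of KO1 against CTL1 and of KO3 against CTL2, which share no library, correlated across the tested genes with r = 0.57, and with r = 0.84 across the more abundant ones. Genes are not independent replicates, so no p-value is attached to these values. The first principal component held 65.7% of the variance and placed CTL1 and CTL2 at -33.1 and -33.6, KO1 at 28.3 and KO3 at 38.4.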

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

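Library totals, DESeq2 size factors, DESeq2 (2255 genes), limma-voom and a separate spread per group kept all counts of calls within 1.5 times. Thinning to equal depth changed the totals too little to test anything. Without a filter on low counts, 1633 genes passed, 810 higher and 823 lower, with 260 at least 2-fold lower. A filter of 5 CPM left 100 genes at least 2-fold higher and 276 lower. Against a 1.5-fold minimum change, 270 genes passed, 118 higher and 152 lower, with 87 and 127 at least 2-fold, and falls made up 60% of the less and 54.4% of the more abundant calls. With both CTL libraries summed, chosen after seeing the data, 152 genes passed, 70 higher and 82 lower, with 40 and 59 at least 2-fold, and 52.2% of the more abundant calls were falls. Cyclic loess, also added, removes trends with abundance by construction and gave falls of 57.1% and 52.2% among less and more abundant calls. Leaving out 1 library gave 120 to 5391 calls, 54 to 2675 higher, 66 to 2716 lower, 37 to 318 and 51 to 775 at least 2-fold higher and lower, and falls of 61.5% to 73.1% and 38.3% to 54.2% among less and more abundant calls. A lone library was taken to vary like the other group. Only few less abundant genes were called without CTL1 and without CTL2. No called gene changed sign in any fit that tested it, which says little, since the groups overlapped for none of them. No paired analysis was possible because the number of column KO3 is in no sample title, so the control it would pair with is not known, and neither of the 2 conceivable pairings was fitted. Leaving the liver gene lists out of the library totals was not run, for lack of symbols.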

Other observations

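Cell cycle genes were the only functional group whose identifiers could be looked up, in the mouse marker pairs of the scran package, and these lists, the split by abundance and the tests of explanations in this part were chosen after the results were seen, though the bound for the comparison of single knockout libraries was set before its value was computed. Genes that mark G2 and M phase had a median log2 change of 0.10 in P1KO. Of 105 tested, 13 were called higher and 8 lower, a share near the 19.5% called over all tested genes. The 6 lists of genes high or low in G1, S or G2/M gave 0 calls with camera, with the smallest p at 0.0641 (adjusted p = 0.332) for the G2/M genes, and 0 of 6 at an unadjusted p below 0.05. With an estimated correlation the adjusted p of that list was 0.57. With no filter on low counts, the list passed at an adjusted p of 0.0432 over 107 genes, so its place near the threshold depended on the filter.

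In the fit to all 4 libraries, 71.8% of the called genes were lower in P1KO among less abundant genes and 41.5% among more abundant ones. The contrast did not extend to large changes, since 68.3% of the more abundant calls of at least 2-fold were falls. Falls were also the majority of the more abundant calls without CTL1, without CTL2, with the CTL libraries summed and against a 1.5-fold minimum change. Few genes passed in these fits. With cyclic loess, which removes trends with abundance by construction, many genes passed, and 1013 of the more abundant were lower and 929 higher. Rises were the majority without KO1 (43.0% lower) and without KO3 (38.3% lower). A difference in depth between the libraries is argued against, since the P1KO libraries held on average 1.07% more counts than the CTL libraries and the shallowest library was CTL1. That only 1 knockout library deviated is argued against as well. The median change of the less abundant genes minus that of the more abundant was -0.17 log2 for KO1 and -0.10 log2 for KO3. Between the CTL libraries it was 0.01 in size. KO3 against KO1 gave medians of 0.04 and -0.02 for the less and the more abundant genes, so these libraries differed too. Both knockout values share the CTL mean, so a shift common to the CTL libraries was not tested. Less RNA from minor cell populations in the knockout preparations may lower many scarce transcripts at once, and it stays open. At equal depth the number of genes with a read in the better P1KO library minus that in the worse CTL library was -191, but without symbols no cell type marker was read, and the genotype itself and a bias by gene length or GC content remain open too.

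The 2 CTL libraries were far closer to each other than the 2 P1KO libraries. Their counts differed, with a chi-square per gene of 2.08, so they are not 1 set of reads deposited as 2 samples. Whether 1 library was sequenced again is not settled by this value. Sampling noise gives 1 only where all counted reads are independent. Both CTL libraries may have been made from the RNA of 1 animal or pool, with a biological coefficient of variation of 3.23% against 12.1% in P1KO, and this cannot be told apart from a true difference in variability, because the labels name no animals. With the CTL libraries summed into 1, edgeR called 152 genes in place of 3027, and 151 of them were among the 3027.

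Among the tested genes, 8 were nearly absent in 1 genotype and present in the other, 3 of them scarce in P1KO and 5 in CTL. A difference in genetic background between the groups may give such genes, as may the loss of Pofut1 itself. Neither was tested, since the 8 identifiers were not placed on chromosomes and the labels name no strain.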
